A study of Mus musculus with 2 samples.

How the data were processed

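The samples were 2 total RNA libraries from the hippocampus of 25-day-old male B6CASTF1/J mice, 1 per biological replicate of 1 group. Per the labels, each library was made from 300 ng of RNA with ERCC spike-ins of a mix named for stranded, ribosome-reduced libraries. Per the text notes deposited with the samples, the tables refer to mm10 and GENCODE annotation release M21, the gene table and the first transcript table were derived from an alignment to the transcriptome, and the second transcript table was derived directly from a read file. Per the file headers, the first 2 have the columns of RSEM and the last those of kallisto. The aligner and the versions of these programs are not given in the sources used here. Nothing was pooled across libraries.

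Per the file headers, the deposited tables give the expected count per gene or transcript, an estimate that shares out reads which match several features and therefore need not be whole. The deposited TPM values divide the expected count by an effective length and scale the sum over all rows, spike-ins included, to the same total in each library. RSEM's effective length was 99 bases below the length of long transcripts, while that of kallisto was 349 bases below it in replicate 1 and 343 in replicate 2. Short transcripts therefore gain TPM relative to their counts. The deposited gene table also gives a posterior SD of the count, used here as a measure of how uncertain the sharing of reads between near-identical genes is.

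The gene table had 81881 rows. Of these, 55536 were annotated genes, all named through the annotation, 96 were spike-ins and 26248 were numbered rows that name no gene. The numbered rows held 6 expected counts in replicate 1 and 2 in replicate 2, spike-ins 112913 and 148536, and a phage control row 0. All of these stayed out of library sizes and ratios. Library sizes were 30635891 and 35713471 expected counts, and 31120487 and 36017567 in the kallisto tables. A count of 0 allows up to 3 counts. Intervals of shares are 95% Wilson intervals and cover counting error only.

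No test between groups was made and no p-values are given. Levels are means ± SD of TPM over 2 replicates. A gene counted as detected at a mean TPM of at least 1. List levels are medians of log2(TPM + 0.1). For the ratio of the replicates, expected counts were rounded to whole numbers and scaled by TMM factors in edgeR 4.0.16 (R 4.3.3), with a prior count of 0.5. The biological coefficient of variation came from edgeR with an intercept only, on genes that passed its expression filter. Genes over 2-fold apart were counted at a mean expected count of at least 100 and set beside 100 Poisson draws of the mean. The median log2 ratio of each list with at least 4 genes of mean expected count 10 or more was placed among 10000 random lists of the same size, drawn gene by gene from 20 bins of mean expression. Lists outside the central 95% were called apart. The 43 lists, 3 groups by rule (ribosomal proteins, mitochondrially encoded genes and histones), the measures above and the rule for named genes were fixed before the data were examined. The difference of the excitatory and inhibitory medians, the 50% threshold for isoforms and the choice of 3 list medians for the alternatives came later. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 did the rest.

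The rule for named genes took the 15 nuclear protein-coding genes with the highest mean TPM, the 3 highest members of each list, the highest member of each list of another region, all members of a list of 6 or fewer where described, the 10 highest and 10 lowest replicate ratios among genes with a mean expected count of at least 100 and mean TPM of at least 1, the top 2 transcripts of the isoform genes, the 5 largest differences in each direction between the tables, and all members of the paired ratios. The text gives values for part of the genes the rule takes and counts for the rest, and some of these genes and a ratio are not reported here. Other genes named, among them further list members, the individual long non-coding RNAs and the small RNAs that lead the TPM, were chosen after their values were seen.

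The ratio and list steps were tested on simulated libraries drawn from the real means and depths with a coefficient of variation of 0.09 and 200 changed genes. Of 94 genes changed 3-fold and measured, 94 were called over 2-fold apart in the right direction, against 3 of 96 changed 1.5-fold and 1 of 12509 unchanged. With no gene changed, the recovered coefficient was 0.0899 over 17675 genes, and 0.113 with the 200 changed genes included. Of 1000 unchanged lists of 8 genes, 5.8% were called apart.

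Alternatives covered the TPM and count minimums, the pseudocount (1 in place of 0.1), DESeq2 1.42.0 size factors, deposited TPM, scaling to spike-ins, the mean in place of the median, the kallisto table, TPM over nuclear genes only, and each replicate left out. For replicate ratios on deposited TPM, 0.5 was added to each value. The kallisto table held 141767 of the transcripts, and 95 were in the RSEM table only. Signal tracks and alignments named in the notes were not used here, and alleles were not analysed here.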

Results

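Total RNA was profiled in the hippocampus (labelled as a layer of it) of male B6CASTF1/J mice, an F1 hybrid strain, at 25 days of age. The labels give 1 group with 2 biological replicates, so no condition was compared. What the data describe is the level of each gene in this tissue and how far the replicates lay apart. The labels call them biological replicates and give them separate tissue sample identifiers but the same donor identifier. Whether they came from separate animals is therefore not settled, and the spread between them may be technical in part or in whole. Each library started from 300 ng of RNA and carried ERCC spike-ins, a set of synthetic RNAs added as a reference. Their mix is named for ribosome-reduced libraries. The gene tables held 30635891 expected counts on annotated genes in replicate 1 and 35713471 in replicate 2. Levels are given in transcripts-per-million (TPM) as the mean ± SD of the 2 replicates, and positions refer to mm10. A gene without counts could still have held up to 3 counts, or 0.0979 counts-per-million in replicate 1 and 0.084 in replicate 2. Such limits cover counting error only.

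In the RSEM gene table, small structural RNAs and mitochondrial ribosomal RNA filled much of the TPM, and neuronal and housekeeping messengers led the nuclear protein-coding genes. Rn7s1 and Rn7s2, near-identical copies of the RNA of the signal recognition particle on chromosome 12 (69159295 to 69159594 and 69361182 to 69361481), together took 28.0% ± 0.118 of TPM (n = 2) but 3.83% ± 0.0358 of expected counts, since they are only 300 bases long. How their reads were split between the copies rests on RSEM, which gave each a posterior SD of 2.82% of the mean count. Rn7sk, a nuclear RNA that restrains transcription elongation, took 5.95% ± 0.356 of TPM. In kallisto, Rn7sk was listed at 0, and Rn7s1 and Rn7s2 each stood at no more than 3.20 TPM in either replicate. Mitochondrially encoded genes took 11.1% in replicate 1 and 11.2% in replicate 2 (17.1% ± 0.189 in kallisto), and the mitochondrial ribosomal RNAs made up 8.38% ± 0.158 of TPM. In expected counts the mitochondrial share was 8.52% in replicate 1 (95% Wilson interval 8.51 to 8.53%) and 8.75% in replicate 2 (8.74 to 8.76%). Protein-coding genes held 47.1% ± 0.320 of TPM and 80.9% ± 0.314 of expected counts.

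Of 55536 annotated genes, 15231 reached a mean TPM of 1, among them 12977 of 22028 protein-coding genes (58.9%) and 302 of 5854 lincRNA genes (5.16%). The number was 15597 in replicate 1 and 14848 in replicate 2. The most abundant nuclear protein-coding genes included Actb at 1567 ± 76.8 TPM (chromosome 5, 142903115 to 142906754) and Camk2a at 1554 ± 98.9 (chromosome 18, 60925618 to 60988152). Camk2a encodes a calcium-dependent kinase of excitatory synapses. Others were the neuropeptide-processing enzyme Cpe (1405 ± 107), the elongation factor Eef1a1 (1320.4 ± 54.3), the ferritin subunit Fth1 (1227 ± 51.7), the lipid carrier Apoe (1140.5 ± 37.7) and the hippocampal calcium sensor Hpca (1135 ± 31.6). Aldoa, Gapdh, Calm3, Cst3, Mbp and Calm2 lay between 947 and 1081. Snurf stood at 1036 ± 35.2 TPM from a 216-base coding model inside the Snrpn locus and was listed at 0 in kallisto. Of 92 cytosolic ribosomal protein genes 89 reached a TPM of 1, and the median of the 92 was 153 TPM.

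Neuronal genes were abundant. All 12 pan-neuronal genes exceeded 10 TPM, with a list median of 293 TPM; the synaptic vesicle protein Syp stood at 858 ± 86.1, the vesicle fusion protein Snap25 at 831 ± 42.0 and the dendritic protein Map2 at 446 ± 11.5. The excitatory neuron list had a median of 89.7 TPM, led by Camk2a, the postsynaptic calmodulin-binding protein Nrgn (755 ± 30.9) and the vesicular glutamate transporter Slc17a7 (664 ± 39.2; chromosome 7, 45163949 to 45176142). The inhibitory interneuron list had a median of 23.3 TPM, with all 16 members above 1. Cck was highest at 313 ± 32.1, then Sst at 199.7 ± 26.6 and the GABA-synthesising enzyme Gad1 at 143 ± 0.219. On the log2(TPM + 0.1) scale the excitatory median exceeded the inhibitory median by 2.01 in replicate 1 and 1.78 in replicate 2. This summary, chosen after the data were seen, compares genes, not numbers of cells.

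Genes that mark each hippocampal field were present. In the dentate granule cell list, 5 of 8 members exceeded 10 TPM, led by C1ql3 (67.4 ± 1.94) and the transcription factor Prox1 (47.1 ± 7.99), and followed by C1ql2 (37.0 ± 1.06). The CA1 list had a median of 32.4 TPM, with Wfs1 at 77.0 ± 5.87, Mpped1 at 73.6 ± 4.86 and Fibcd1 at 53.7 ± 6.85. The CA2 list had a lower median of 8.425 TPM, with 3 of 7 members above 10. These were Pcp4 (122 ± 2.80), Necab2 (45.8 ± 4.12) and Rgs14 (40.3 ± 0.0212), while Map3k15 stayed at 0.635 ± 0.0354. The CA3 list had a median of 23.6 TPM, led by Homer3 (35.2 ± 2.08), Bok (33.9 ± 0.983) and the kainate receptor subunit Grik4 (25.0 ± 1.26). Hilar mossy cell markers were low apart from Calb2 (21.4 ± 2.95), which interneurons share; Calcrl stood at 4.02 ± 0.219, Drd2 at 1.495 ± 0.106 and Csf2rb2 at 0.715 ± 0.262. The subiculum markers were Fn1 (22.8 ± 2.19), Slc17a6 (7.28 ± 2.35), Nts (5.27 ± 0.891) and Ly6g6e (2.28 ± 0.622).

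Of 9 progenitor and immature neuron genes, 8 reached a TPM of 1 and 4 exceeded 10, while the cell division list had a median of 0.560 TPM. Hopx, also an astrocyte gene, stood at 38.5 ± 0.629, Sox2 at 23.0 ± 0.205 and Neurod1 at 16.7 ± 0.686. Dcx, a marker of immature neurons, was at 10.2 ± 0.495, and Eomes, of intermediate progenitors, at 0.630 ± 0.0849. Only 2 of 6 cell division genes reached a TPM of 1. These were Pcna (21.3 ± 1.57), which also serves DNA repair, and Top2a (1.34 ± 0.382), while Ccnb1 (0.580 ± 0.0566), Mki67 (0.540 ± 0.0283), Birc5 (0.445 ± 0.134) and Cdk1 (0.245 ± 0.120) were below it. Of the Cajal-Retzius list, Reln (20.7 ± 2.34) and Ndnf (9.62 ± 0.233) are also interneuron genes, while Trp73 (1.15 ± 0.255), Lhx1 (0.185 ± 0.00707) and Lhx5 (0.045 ± 0.00707) were low.

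Astrocyte and myelin genes were abundant. All 10 astrocyte genes exceeded 10 TPM, led by the glutamate transporter Slc1a2 (914 ± 28.0), Aldoc (383 ± 22.2) and Slc1a3 (180 ± 0.813). The myelinating oligodendrocyte list had a median of 106 TPM, with the myelin proteins Mbp at 949.9 ± 28.3 (chromosome 18, 82475146 to 82585637) and Mobp at 262 ± 5.67. Precursor and newly formed oligodendrocyte lists were lower, with medians of 20.2 and 8.16 TPM. Their leading members were Olig1 (72.0 ± 5.25), Ptprz1 (62.6 ± 3.41) and Pdgfra (20.3 ± 1.94) for precursors, ahead of Olig2 (15.5 ± 0.516) and Cspg4 (9.40 ± 1.80), and Bcas1 (32.3 ± 0.255), Gpr17 (27.2 ± 1.15) and Enpp6 (8.74 ± 1.34) for newly formed cells, ahead of Tmem163 (7.58 ± 0.120), Neu4 (6.68 ± 0.226) and Bmp4 (2.28 ± 0.318). All 12 microglial genes were detected, with a median of 15.9 TPM and members such as Csf1r (35.2 ± 0.212) and P2ry12 (22.6 ± 0.573). Of 5 perivascular macrophage genes only Mrc1 exceeded 1 TPM (1.44 ± 0.170).

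Vascular, fibroblast, choroid plexus and ependymal lists had medians from 0.570 to 7.26 TPM, and the blood list had a median of 270.4. The endothelial median was 7.26 TPM (Cldn5 22.2 ± 3.16, Ly6c1 21.5 ± 1.42, Slco1a4 18.6 ± 2.17) and the mural median 4.12 TPM (Vtn 24.0 ± 0.940, Rgs5 22.1 ± 0.587, Pdgfrb 7.43 ± 0.460). Fibroblast genes had a median of 7.24 TPM, led by Igf2 (33.6 ± 3.66) and Dcn (15.6 ± 6.26). Haemoglobin genes were high and variable, at 325 ± 111 for Hba-a1, 299.7 ± 66.8 for Hbb-bs and 270.4 ± 70.7 for Hba-a2, with Hbb-bt at 38.0 ± 8.01 and the erythroid enzyme Alas2 at 4.16 ± 0.219. The choroid plexus transcript Ttr stood at 54.5 ± 9.29, whereas the next member, Kl, was at 3.78 ± 0.00707 and 8 of the 12 members were under 1. The ependymal list peaked at Rarres2 (6.44 ± 0.841).

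The neocortex list had a median of 11.7 TPM, the thalamus list 9.76 and the striatum list 1.56, and genes of distant cell bodies were nearly absent. The highest members were Fezf2 (20.005 ± 3.16) for neocortex, Ntng1 (12.7 ± 1.28) for thalamus and Ppp1r1b (20.2 ± 1.29) for striatum; some of these genes are also expressed in hippocampus. Striatal Drd1 stood at 1.79 ± 0.0424 TPM and Adora2a at 1.34 ± 0.403. None of the 4 cholinergic or 5 monoaminergic genes reached a TPM of 1, with Chat at 0.010 ± 0.0141 and Th at 0.20 ± 0.0141. Of 6 hypothalamic peptide genes only Pomc did (1.495 ± 0.177), and Agrp and Pmch had 0 counts in both libraries. Calb1, on the cerebellar list but also a granule cell gene of the dentate gyrus, stood at 72.4 ± 4.08, while Gabra6 was at 0.145 ± 0.0919.

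**Figure D1:**
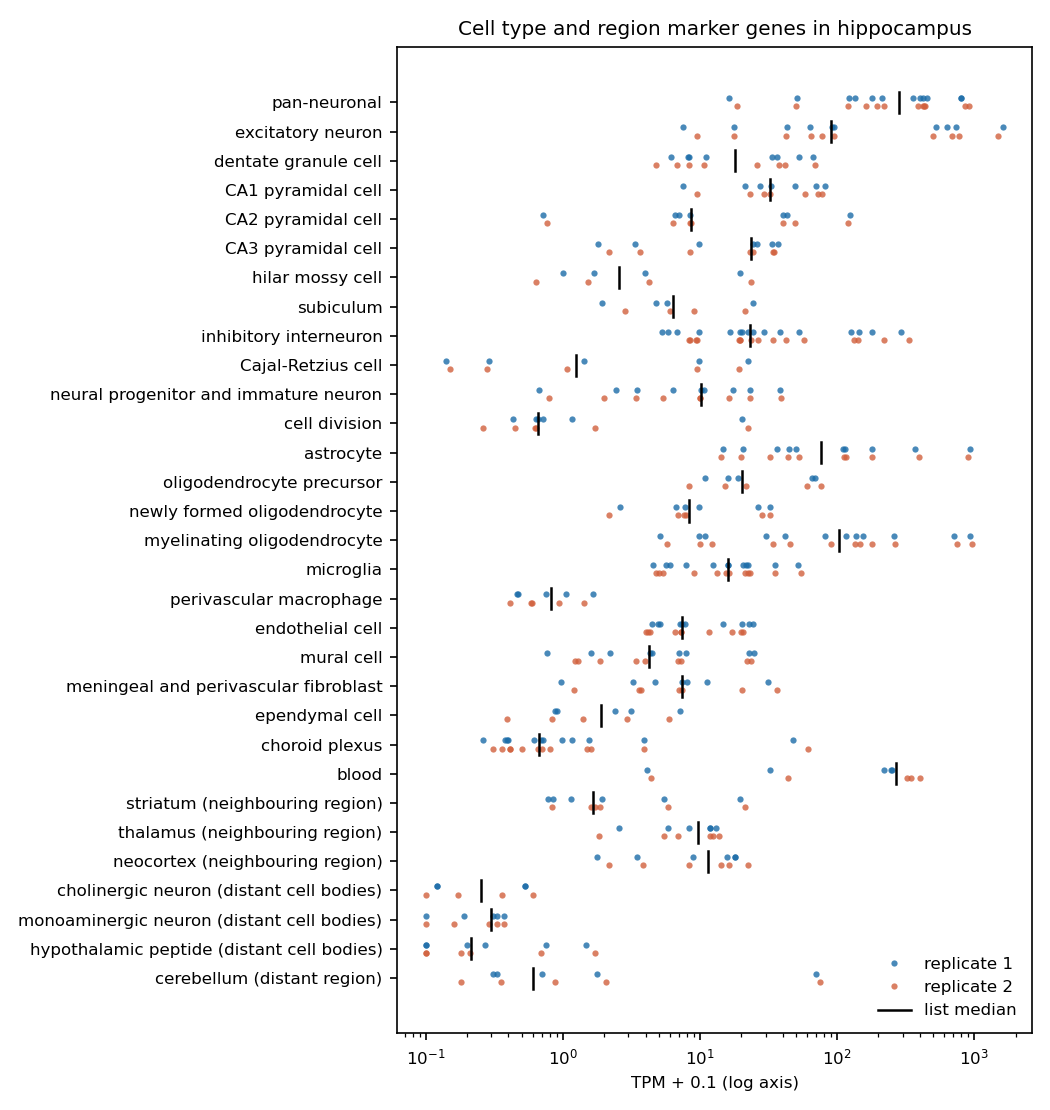
Level of each marker gene (points, TPM + 0.1 on a log axis) by list in replicate 1 and replicate 2 of the hippocampus group, with vertical bars at the list median. Pan-neuronal genes centre on 293 TPM, excitatory on 89.7 and inhibitory on 23.3, and the medians of the lists of distant cell bodies lie below 1.

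Glutamate and GABA receptor genes covered a wide range. Gria1 (304 ± 8.99) and Gria2 (275 ± 21.6) led the AMPA and kainate list, followed by Grik5 (110 ± 5.85). Of the NMDA receptor genes, Grin1 stood at 199.6 ± 11.2, Grin2a at 158 ± 27.3 and Grin2b at 157 ± 25.2, whereas Grin3b was at 0.045 ± 0.00707. Grm5 (105 ± 2.39), Grm2 (32.8 ± 4.21) and Grm7 (30.8 ± 3.38) were the highest metabotropic receptors, and Grm6 had 0 counts. Among 12 GABA-A receptor genes, all above 1 TPM, Gabra5 stood at 87.3 ± 1.17 and Gabrb2 at 63.0 ± 2.40.

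Paired genes were compared as ratios within each library. Grin2a over Grin2b, a pair whose balance shifts during postnatal development, was 1.02 in replicate 1 and 0.999 in replicate 2, so neither gene exceeded the other beyond the spread; on expected counts, which are not divided by length, the ratio was 0.692. The chloride exporter Slc12a5 stood at 9.72 ± 0.109 times the importer Slc12a2. Slc17a7 stood at 113 times Slc17a6 in replicate 1 and 77.4 times in replicate 2. Gad1 stood at 0.216 ± 0.0130 of Slc17a7 and at 3.57 ± 0.229 of Gad2, the latter falling to 1.55 on expected counts. The other ratios were 1.11 ± 0.0544 for Gria1 over Gria2, 3.02 ± 0.0879 for Camk2a over Camk2b, 47.0 ± 3.12 for Mbp over Pdgfra and 0.0843 ± 0.00322 for Dcx over Rbfox3. On expected counts Mbp over Pdgfra was 15.7, Dcx over Rbfox3 0.224 and Slc12a5 over Slc12a2 6.44.

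In 14 of 23 genes examined for isoforms in RSEM, the leading transcript took at least 50% of the gene's TPM. This threshold was set after the data were seen. The number was 11 in kallisto, and 13 in RSEM without replicate 1. The leading transcript was the same in both replicates for all 23 genes in the RSEM table, and in both replicates and both tables for 22. App-201 took 91.1% ± 0.137 of App, against 4.52% ± 0.419 for App-202. Gfap-201 took 90.6% ± 1.37, Snap25-201 87.6% ± 0.356 and Camk2b-209 84.1% ± 2.87. Mapt-204, with 10 exons, took 68.7% ± 2.35. The short Homer1-207 (6 exons, 579 coding bases) led Homer1 with 30.6% ± 1.76, ahead of Homer1-203 (10 exons, 1098 coding bases) with 25.2% ± 0.805. For Ntrk2 the 12-exon Ntrk2-202 (36.2% ± 0.718) exceeded the 18-exon Ntrk2-201 (28.8% ± 0.540). The exception between the tables was Mbp, where Mbp-211 took 67.8% ± 1.19 in RSEM but 26.3% ± 3.60 in kallisto, behind Mbp-201 with 29.1% ± 0.472 on the mean. In kallisto, Mbp-211 was behind in replicate 1 only (23.8% against 29.4%). In replicate 2 the 2 transcripts were level (28.9% against 28.8%).

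All 18 immediate early, 7 heat shock and 13 clock genes exceeded 1 TPM. Immediate early genes ran from Homer1 (76.2 ± 0.877), Arc (48.2 ± 6.55) and Egr1 (41.1 ± 3.17) to Egr2 (1.08 ± 0.212). The chaperones Hspa8 (921 ± 29.1), Hsp90aa1 (402 ± 42.5) and Hsph1 (140 ± 1.60) led the heat shock list, and Hspa1a was at 6.69 ± 0.481. Clock genes ran from Tef (106 ± 7.30), Cry2 (44.2 ± 1.05) and Nr1d1 (38.0 ± 1.84) to Cry1 (4.36 ± 0.127). Only Ifi27 (32.1 ± 0.820) and Bst2 (1.58 ± 0.219) of 8 interferon response genes reached 1 TPM.

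The lists of imprinted genes, whose expression can depend on the parent of origin, included some abundant transcripts. The data do not separate the parental alleles. On the maternal list Meg3 stood at 1040.1 ± 307 (chromosome 12, 109541001 to 109571726), Gnas at 789 ± 74.9 and Rian at 465 ± 55.2. On the paternal list Snhg14 stood at 669 ± 140, Snrpn at 377 ± 20.4 and Nnat at 253 ± 35.8. The Y-linked genes Eif2s3y (28.9 ± 4.20), Ddx3y (21.1 ± 0.354), Uty (9.32 ± 0.757) and Kdm5d (8.11 ± 0.382) were expressed, and Xist, the RNA that coats an inactive X chromosome, stood at 0.110 ± 0.0283. The samples are labelled male.

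The replicates were close for most genes. Across the 15231 genes with a mean TPM of at least 1, Pearson's r of log2(TPM + 0.1) was 0.964 and Spearman's rho 0.985; genes are not independent replicates. The common biological coefficient of variation was 0.0920 over 17576 genes, with an SD of the log2 ratio of 0.36. Of 12719 genes with a mean expected count of at least 100, 99 (0.778%) lay over 2-fold apart, 17 higher and 82 lower in replicate 2. The number was 54 on deposited TPM with 0.5 added to each value (14 higher, 40 lower) and 186 in kallisto (14 and 172). Of these, 49 and 68 were shared with the 99 in direction. The added 0.5 TPM pulls ratios of genes at a few TPM toward 0. Gm43320, at 2.57 and 0.71 TPM, scored -1.34 there and -1.80 on scaled counts. The 54 and the 99 are therefore not on the same scale. Poisson sampling of the mean, which stands for 1 library counted again, gave 0 such genes in each of 100 draws. This does not separate biological from technical spread. Spike-ins took 0.367% of expected counts in replicate 1 (95% Wilson interval 0.365 to 0.369%) and 0.414% in replicate 2 (0.412 to 0.416%). Scaling to the spike-ins therefore moved the median log2 ratio from 0.04 to -0.17, so the directions that follow are relative to the other genes of the same libraries.

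TEC, sense-intronic and nuclear-retained long non-coding RNAs were lower in replicate 2. Of the 82 genes over 2-fold lower there, 69 were TEC genes, an annotation class for transcribed regions still awaiting experimental evidence, and 6 were sense-intronic genes. The median log2 ratio of replicate 2 over replicate 1 was -0.90 over 174 TEC genes and -0.80 over 20 sense-intronic genes, against 0.04 over 11905 protein-coding genes; with spike-in scaling the medians were -1.10, -1.01 and -0.16. The median was also below 0, at -0.15, over 138 lincRNA genes (95 lower) and over 87 processed transcripts (60 lower). It was -0.02 over 59 antisense genes and 0.16 over 192 processed pseudogenes. Without the TEC and sense-intronic classes, 24 genes were over 2-fold apart. The list of nuclear-retained long non-coding RNAs moved likewise, with 6 of 7 members lower and a median of -0.61, below all 10000 random lists of matched expression (percentile 0). Malat1 (chromosome 19, 5795690 to 5802672) had 6248 TPM in replicate 1 and 3857 in replicate 2, a log2 ratio of -0.70. The others were Meg3 (-0.64), Neat1 (-0.62), Snhg11 (-0.61), Miat (-0.61), Rmst (-0.27) and Pantr1 (0.06).

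The 10 lowest ratios among genes with at least 1 TPM included 5 TEC genes (Gm43320, Gm38198, Gm42993, AC164106.1 and Gm42768, from -1.80 to -1.43) and the sense-intronic Gm10862 (-1.45). Xlr3b, on the X chromosome (73192207 to 73202930), belonged to them at -1.77, with 241 expected counts in replicate 1 and 79.7 in replicate 2. The remaining 3 were 1700047I17Rik2 (334 and 0 counts), Gm10222 (330 and 0.3) and Gm6361 (206 and 0.83), but RSEM's own posterior SD of their counts was 95.9%, 294% and 107% of the mean count, so their values are uncertain. The 10 highest ratios had large posterior SDs too, from 38.4% to 117% of the mean count. They were Gm11847, with 0 counts in replicate 1 and 431 in replicate 2, and Gm24497, Fam220a, Myl12b, Gm20458, Gm10359, Gm13394, Gm5559, Gm6565 and Gm13370, with log2 ratios from 1.62 to 9.36. Genes with a small posterior SD, chosen after their values were seen, included Dlk1 (1.36, with 61 and 179 counts) and Npas4 (0.89, with 179 and 380 counts).

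**Figure D2:**
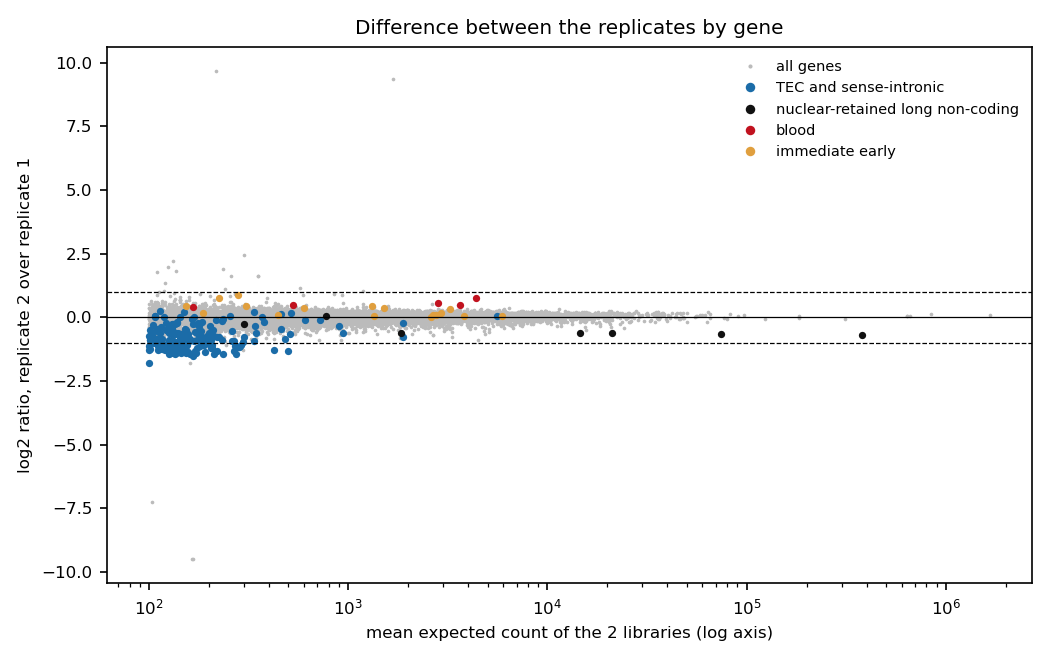
Log2 ratio of replicate 2 over replicate 1 (vertical axis) against the mean expected count of the 2 libraries (log axis) for each of 12719 genes with a mean count of at least 100; dashed lines mark 2-fold. TEC and sense-intronic genes lie mostly below 0, as do 6 of 7 nuclear-retained long non-coding RNAs, and blood genes lie above 0.

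Of 41 lists with at least 4 measured genes, 10 had a median log2 ratio above the central 95% of random lists and 5 below it, where chance would give 2.1 in all. Of these 15 lists, 9 lay outside under every other setting that gave a value. The random lists had a median of 0.06 for the pan-neuronal list, -0.04 for histones and -0.01 for the subiculum list. As background to the member counts below, 4501 of 11905 protein-coding genes with a mean expected count of at least 100 were lower in replicate 2. Blood genes were higher in replicate 2 in 5 of 5 members, with a median of 0.51 (percentile 100) and Hba-a1 at 247 and 403 TPM. Immediate early genes were higher in 18 of 18 members, with a median of 0.25 (percentile 100), led by Npas4 and Fos (0.77). Heat shock genes were higher in 7 of 7 (median 0.19, percentile 99.7), interneuron genes in 14 of 16 (0.18, percentile 100), pan-neuronal genes in 12 of 12 (0.16, percentile 99.9) and myelin genes in 11 of 12 (0.16, percentile 99.8). The subiculum list had a median of 0.40 over 4 genes (percentile 99.9), with Slc17a6, Nts and Ly6g6e higher and Fn1 at -0.07. Replication-dependent histones (50 of 64 higher, median 0.17) and cytosolic ribosomal proteins (81 of 89 higher, median 0.12) also lay above the random lists. Relative to protein-coding genes of like GC content and length, the medians were 0.07 for histones, 0.04 for ribosomal proteins, 0.12 for interneuron genes and 0.10 for myelin genes. Spike-in scaling lowers every list by the same amount and leaves the percentiles as they are; the medians of the pan-neuronal, interneuron, myelin, heat shock, histone, ribosomal and paternally imprinted lists are below 0 on that scale.

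Endothelial genes were lower in replicate 2 in 9 of 10 members, with a median of -0.14 (percentile 0.43; 2.83 by the mean, inside the range). Maternally imprinted genes had a median of -0.19 (percentile 0.17) but 4 of 9 members were higher, and by the mean their percentile was 24.1. Paternally imprinted genes had a median of 0.12 (percentile 98.8; 97.2 on TPM, inside the range). The sex-linked list (median -0.22, percentile 1.95) and the mitochondrial list (-0.03, percentile 1.42) each came inside the range on TPM, at percentiles 19.1 and 4.83, and in kallisto, at 3.16 and 40.5, where the mitochondrial median was 0.09. Ribosomal proteins came inside it when ratios were compared with genes of like GC content and length (percentile 97.0). The excitatory, astrocyte, microglia, dentate, CA1, CA2 and CA3 lists lay inside the range, at percentiles from 5.67 to 85.0. By the mean, the dentate list came below the range (percentile 1.74; 2.29 on TPM) and the CA1 list above it (97.7; 98.5 on TPM). With 1 library on each side, these values describe these libraries.

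**Figure D3:**
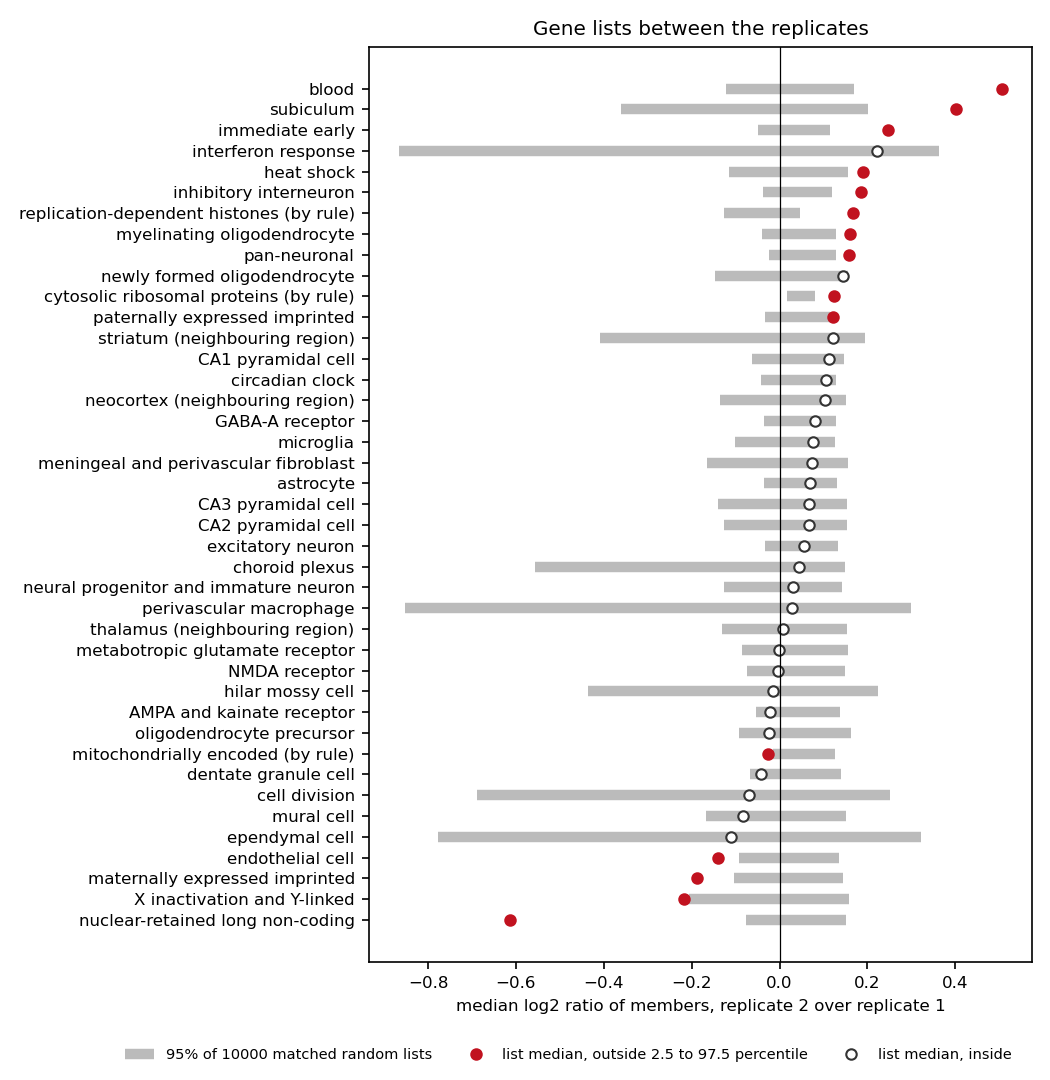
Median log2 ratio of replicate 2 over replicate 1 for 41 gene lists (points), with grey bars spanning 95% of the medians of 10000 random lists of the same size and matched expression. Blood (0.51) and subiculum (0.40) lie highest and nuclear-retained long non-coding RNAs (-0.61) lowest.

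The transcript tables made with RSEM and kallisto were compared within each library. Over 141767 transcripts, Pearson's r of log2(TPM + 0.1) between RSEM and kallisto was 0.770 in replicate 1 and 0.777 in replicate 2, with Spearman's rho of 0.741 in both; among transcripts with at least 1 TPM in either table r was 0.366 and 0.379. Summed by gene, the median kallisto value exceeded RSEM by 0.68 in replicate 1 and 0.65 in replicate 2 on the log2 scale. Of 18082 genes with at least 1 TPM in either table, 2951 were over 2-fold higher and 566 over 2-fold lower in kallisto in both libraries. After subtraction of the median difference the numbers were 1361 and 643. The largest gaps downward were Rn7sk, Rn7s1, Rn7s2, Rmrp and mt-Atp8, all of 331 bases or fewer. Rn7sk stood at 61987 and 56955 TPM in RSEM and was listed at 0 in kallisto. The largest gaps upward were Gm47283, Gm47673, Gm28439, Gm26905 and Gm48765, which RSEM put at or below 0.07 TPM and kallisto between 28.2 and 220.5 TPM.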

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

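The numbered rows, which name no gene and enter no comparison, together held 6 expected counts in replicate 1 and 2 in replicate 2. The sum of 6 was flagged for exceeding the 3 counts that a count of 0 allows. That limit stands for 1 gene, while the sum runs over 26248 rows, so it does not judge them. No biological explanation was tested, and no test was chosen after the result was seen.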

How the results depend on the processing

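Spike-in scaling of lists, GC and length matching, subtraction of the median difference, the 4 added pseudogenes, the exclusions of gene classes and the 3 single list medians were chosen after the data were seen. With 2 libraries, no list ratio could be left out by replicate, and no paired analysis was possible because there is 1 group. The number of genes detected stayed within 1.5 times of its main value under all 7 alternatives, and so did the number of lists apart (13 to 16 of 33 to 41 lists) under 5. The nuclear-retained, blood and immediate early lists kept their direction and their side of the range under those 5. Spike-in scaling moves all lists alike, so it tests neither. Where values moved, the cause was not tested unless stated. The mitochondrial share was 8.63% on expected counts, 17.1% in kallisto and 13.1% with 4 nuclear pseudogenes added. The spike-in share was 0.739% of TPM. The excitatory minus inhibitory median ranged from 1.78 to 2.01 with a replicate left out. The coefficient of variation was 0.0927 with DESeq2 size factors, 0.103 without a filter, 0.0853 at 100 counts and 0.134 in kallisto. The SD of the log2 ratio was 0.28 on TPM, 0.97 without a filter, 0.28 at 100 counts and 0.42 in kallisto. Ratios on TPM here have 0.5 added to each value, which pulls those of genes at a few TPM toward 0. Genes over 2-fold apart numbered 54 on TPM (14 higher, 40 lower), 154 with spike-ins (12 and 142), 936 at 10 counts (120 and 816), 2 at 1000 counts, 186 in kallisto (14 and 172; 68 genes shared with the main result) and 24 without TEC and sense-intronic genes (17 and 7). Without genes of large posterior SD there were 80 (2 and 78). Pearson's r between the tables was 0.794 at pseudocount 1 and 0.372 for transcripts of at least 1 TPM. Genes apart between the tables numbered 2307 at pseudocount 1 and 2004 after centring. On expected counts, which keep transcript length, the ratios were 0.692 for Grin2a/Grin2b, 6.44 for Slc12a5/Slc12a2, 1.55 for Gad1/Gad2, 0.170 for Gad1/Slc17a7, 1.28 for Gria1/Gria2, 15.7 for Mbp/Pdgfra and 0.224 for Dcx/Rbfox3. In kallisto they were 1.23, 8.59, 2.57 and 0.155 for the first 4, 3.25 for Camk2a/Camk2b and 43.4 for Mbp/Pdgfra. Grin2a/Grin2b ranged from 0.999 to 1.02 with a replicate left out, so its side of 1 is not settled. Of the single list levels, 42 of 43 moved by more than the replicate SD in kallisto, 36 by the mean, 30 over nuclear genes and 27 at pseudocount 1. TPM over nuclear genes scales all genes of a library alike, and kallisto values carry a shift of all genes. Those 2 counts therefore do not by themselves show lists moving against each other. The excitatory minus inhibitory median was 1.94 in the main setting, over nuclear genes and in kallisto. Depth limits what can be said of genes under 10 counts, whose list ratios were not examined.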

Other observations

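The tests of shared reads between the replicates, and those between the tables of shared reads and effective length by direction, of the median difference, of the small RNAs left out and of transcripts shorter than the assumed fragments, were chosen after the result was seen, as were the genes named in the next paragraph. The test of genomic DNA on olfactory receptor genes was added once the first test of genomic DNA was known.

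Among genes with a posterior SD under 10% of the mean count and outside the TEC and sense-intronic classes, the highest ratios of replicate 2 over replicate 1 included the imprinted Dlk1 (1.36), the fibroblast gene Dcn (0.87), Tpbg (0.86) and Syt9 (0.79), beside Npas4, Hba-a1 and Fos. Eif6 (0.87; chromosome 2, 155819832 to 155826925) and its neighbour BC029722 (1.03; 155817730 to 155819426) were both among the 10 highest, with 601 and 1255 counts for Eif6 and 710 and 1654 for BC029722. The lowest were mostly lincRNA genes, along with Xlr3b, Slc26a10 (-0.90) and the imprinted antisense RNA Kcnq1ot1 (-0.88). Both lists describe this pair of libraries only.

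Against protein-coding genes of like GC content and length, the median log2 ratio of TEC and sense-intronic RNA was still -0.91 (95% bootstrap interval -0.97 to -0.82, 194 genes), which argues against a bias of that kind as the whole cause of its lower level in replicate 2. A different mix of cells that moves host genes and the RNA inside them alike is argued against for 135 pairs. The median of inner RNA minus host gene was -0.95 (-1.03 to -0.86). It cannot decide on a mix of cells that differ in their share of unspliced RNA, nor on genes without a host. Bootstrap intervals here cover spread over genes in this 1 pair of libraries, not spread between libraries. Genomic DNA in replicate 1 would cover silent genes too, yet 1135 olfactory receptor genes held 0.185 counts per kb there, 0.700% (0.449 to 0.970%) of the 26.4 counts per kb by which the TEC and sense-intronic genes exceeded depth-scaled replicate 2. A larger share of unspliced RNA in replicate 1 is a candidate explanation, since the median of retained-intron minus protein-coding transcripts of the same gene was -0.52 (-0.54 to -0.50, 2371 genes), and the median of genes inside a host on the same strand lay below that of genes outside or opposite (difference -0.56, -0.74 to -0.32). The 47 genes outside any protein-coding gene had a median of -0.57, for which a host gene is no explanation, so that part stays open, and beyond the mix of cells and the share of unspliced RNA no biological explanation was tested.

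The 17 genes over 2-fold higher in replicate 2 may mostly reflect reads shared between near-identical copies: 88.2% (15 genes; exact 95% interval 63.6 to 98.5%) had a posterior SD of at least 10% of the mean count, against 1.51% of all genes at that depth. The same does not hold for the 82 lower genes, of which 4.88% (4 genes; 1.34 to 12.02%) did. No biological explanation was tested.

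With Rn7s1, Rn7s2 and Rn7sk left out and TPM rescaled in both tables, the median log2 difference between the tables was 0.081 (95% bootstrap interval 0.076 to 0.086) in place of 0.67, so these RNAs are a candidate explanation of the shift of all genes, and removing the median left 53.9% (52.1 to 55.7%) of the 2951 genes higher in kallisto no longer over 2-fold apart, as any cause of a shift would. Effective length stays open: at the effective length of RSEM 51.2% (exact 95% interval 49.4 to 53.0%) of the higher genes stayed over 2-fold higher, while the 100% of the 566 lower genes that stayed lower decide nothing, since this conversion can only lower kallisto values, and counts-per-million, on which 47.3% of all 3517 genes stayed apart, also remove the shift. For the lower genes there are 2 candidate explanations: 59.4% (55.2 to 63.4%) were shorter than the fragments kallisto assumed, against 2.47% of all genes, and of 563 with a posterior SD 49.9% (45.7 to 54.1%) had one of at least 10% of the mean count, against 4.72% of all genes. Of the higher genes 2401 had a posterior SD, and 10.1% (8.94 to 11.4%) exceeded that limit, or 17.7% over both directions, but the SD does not see reads that RSEM gave to another copy, so shared reads stay open there. No biological explanation was tested.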
